A study of Mus musculus with 16 samples.

How the data were processed

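Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in neural progenitor cells made from V6.5 mouse embryonic stem cells. Per the labels' protocols, the cells passed through embryoid bodies for 4 days and were crosslinked with 1% formaldehyde. Cells of the knockdown arms were transfected with an siRNA against luciferase (control) or against Cbx3, 72 hours before harvest. Files of 9 ChIP libraries were analysed, and the 7 input libraries were not used here on their own.

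Each deposited file lists windows of 50 bp, each with a signal value made by the authors. The submitters' processing notes name Bowtie and the genome build mm9, with no version of the aligner. The window test, its threshold and the use of the inputs are not given in the sources used here. In every file the values were whole multiples of 1 step, to within 0.05 of a step. Multiples of 50 steps were the most frequent remainder of the 50 possible in every library. They made up 19.5 to 22.3% of values in Cdk8 and Cbx3 set 2, but only 2.59 to 3.41% in the Pol II libraries, against 2% by chance. They were read here as whole reads covering a window, a reading inferred from the values and weakest for Pol II. The step was 0.0192 in both Med26 libraries, 0.0282 in both Cdk8 libraries and 0.0220 in both siRNA Pol II libraries, so 1 read carries the same value in both files of a pair. Values within a pair were compared as deposited; an equal step does not show equal depth, and comparability was not tested. It was 0.0797 and 0.0436 in Cbx3 sets 1 and 2 and 0.0211 in untreated Pol II, and levels were not compared across those libraries except where stated. Total reads per library are unknown from such lists, which hold only windows above a minimum. A window missing from a list can therefore hold signal just below that minimum.

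Windows up to 200 bp apart were merged into regions, and a region's signal was that of its highest window. Regions overlapped when they shared at least 1 bp. Chance overlap was measured with 100 circular shifts of the regions within their chromosomes. Shares carry 95% Wilson intervals, and medians of log2 ratios carry binomial intervals of the order statistics; both cover counting error only, since neighbouring windows share reads and regions are not replicates. Groups of regions were set against 10000 random lists with the same number of regions per signal class, drawn from all regions of the comparison. Each siRNA arm had 1 library per antibody, so differences between arms have no replicate check and no p-value is given. Cbx3 had 2 libraries, and Cbx3 regions were those of set 1 that overlapped set 2.

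The promoter and gene list comparisons fixed before the data were examined were not run, because the gene table used here is of another genome build (GRCm38) and coordinates were not converted. The region-level comparisons fixed in their place were run. The naming rule for genes was carried over to regions: for each siRNA pair the 10 merged regions with the largest fall and the 10 with the largest rise in listed length, and for Cbx3 and untreated Pol II the 10 longest, taking the shorter length of the 2 Cbx3 sets. The comparison of Med26 at regions with and without Cbx3 was planned for promoters, and its region form was chosen after the data were seen. Alternatives covered the minimum overlap, the signal threshold, equal numbers of regions, merging and each Cbx3 set alone.

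The overlap, merging, shift and matched-list steps were tested on simulated data with 5000 regions per list. A simulated overlap of 40% was found as 40%, and a chance overlap of 1.50% as 1.47%. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are those of the files, counted from 1.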

Results

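Genome occupancy was mapped for Cbx3 (the heterochromatin protein HP1 gamma) and RNA polymerase II (Pol II) in untreated neural progenitor cells. Med26, a subunit of the Mediator coactivator, Cdk8, the kinase of its detachable module, and Pol II were mapped after control siRNA or Cbx3 siRNA. Cbx3 had 2 libraries (sets 1 and 2) and every other group had 1. The files listed 923942 and 244855 windows of 50 bp for Cbx3 sets 1 and 2, and 34855 for untreated Pol II. Under control and Cbx3 siRNA they listed 15546 and 2721 windows for Med26, 9960 and 10955 for Cdk8, and 116001 and 101091 for Pol II. On the inferred signal of 1 read, the median listed window held the equivalent of 8.48 and 6.24 reads in the Cbx3 sets, 6 in both Cdk8 libraries, 10.2 and 8.24 in Med26, and 15.1 and 13.4 in the siRNA Pol II libraries, where that inference is weakest. The level of Cbx3 after the knockdown was not analysed here.

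The first comparison asked where Cbx3 lies in untreated cells and how far its 2 libraries list the same sites. The longest regions listed in both sets lay on chromosome Y from 2875151 to 2902650, with 27500 bp listed in set 1 and 17450 bp in set 2, and on chromosome Y from 2847451 to 2868750, with 20600 and 6900 bp. A region on chromosome 11 from 3080551 to 3100100 followed, with 19350 and 5250 bp. Others of the 10 longest were on chromosome 17 from 39979851 to 39983750 and on chromosome 8 from 125950201 to 125954150. The chromosome 17 region lies in a stretch listed in all 9 libraries, so it is not particular to Cbx3. Since the inputs were not used, signal not particular to Cbx3 cannot be told apart at these regions or at those of highest signal. Genome-wide, 13986 of the 126451 regions of set 2 overlapped set 1 (11.1%, interval 10.9 to 11.2%), against 3.42% after shifting. The overlap was 4.66% in the lowest decile of set 2 regions by signal and 40% in the highest. The highest signals of set 2 lay on chromosome 2 from 98506251 to 98507600 (signal 291644), and 163 such regions above 10 times the median held 53.8% of the summed signal of that set. Most regions of either set were thus listed in that set alone, which limits every statement below that uses Cbx3.

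Cbx3 and Pol II shared sites in untreated cells more often than shifted regions did. Of 8183 untreated Pol II regions, 445 held Cbx3 called in both sets (5.44%, interval 4.97 to 5.95%), against 0.287% after shifting. Set 1 alone covered 36.9% of them and set 2 alone 8.91%, against 5.33% and 1.60% after shifting. The reverse share was small: 433 of the 13802 Cbx3 regions of both sets (3.14%) held untreated Pol II. The longest untreated Pol II regions were on chromosome 3 from 128916551 to 128920250 (3500 bp listed), chromosome 8 from 73222201 to 73224100 (1700 bp) and chromosome 17 from 36053851 to 36055900 (1650 bp). Med26 and Cdk8 regions under control siRNA held Cbx3 of both sets in 4.44% and 4.77% of cases, against 0.238% and 0.209% after shifting. The share depended on the Cbx3 set used, as Cbx3 set 1 alone covered 25.2% of the Med26 regions and 13.9% of the Cdk8 regions.

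**Figure D1:**
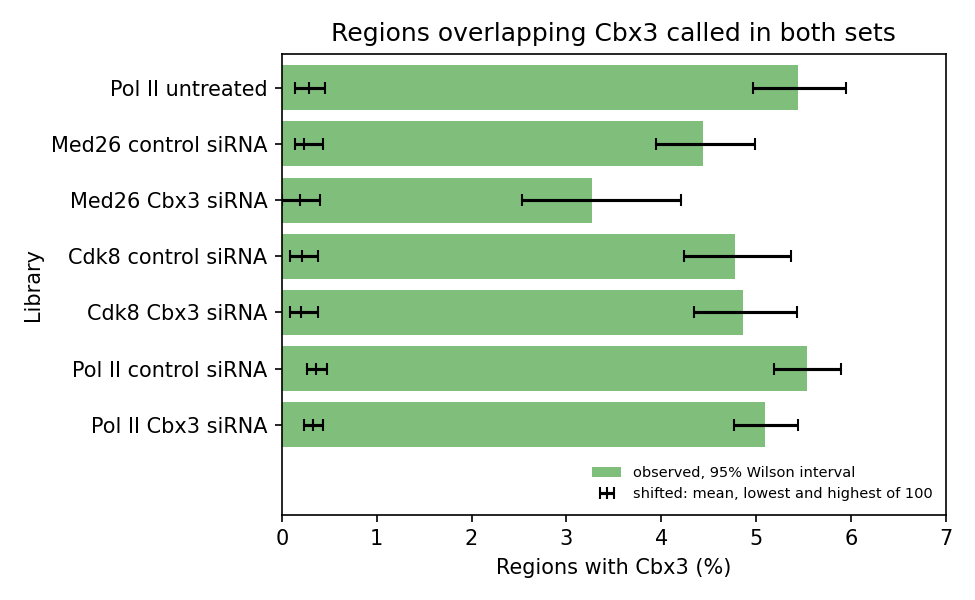
Bars give the percent of each library's regions that overlap Cbx3 called in both sets, with 95% Wilson intervals, and black marks give the mean and range of 100 circular shifts. All 7 libraries lie between 3.27% and 5.53%, above every shifted value.

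The next comparisons asked whether Med26, Cdk8 and Pol II occupancy differed after Cbx3 knockdown. Med26 was listed over 777 kb under control siRNA and over 136 kb under Cbx3 siRNA. Of its 5990 control regions, 516 were also listed after the knockdown (8.61%, interval 7.93 to 9.35%). The largest losses were on chromosome 15 from 96116851 to 96117750, with 900 bp listed in the control and none after the knockdown, and on chromosome 4 from 57969051 to 57970100 and from 117852101 to 117853150, each with 850 bp and none. On chromosome 3 from 95118751 to 95119600, 850 bp became 100 bp. Pol II of the untreated and control libraries lay at all 10 regions with the largest losses and at 9 of the 10 with the largest gains. The largest gain, on chromosome 4 from 116961751 to 116962350, went from 150 to 500 bp. In the reverse direction, 516 of the 1745 regions listed after the knockdown were in the control list (29.6%) and 1229 were not. Pol II of the same knockdown lay at 90.9% of the former and 27.4% of the latter.

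Med26 control regions at Pol II were kept more often (499 of 4484, 11.1%) than those away from Pol II (17 of 1506, 1.13%). Regions at Pol II also had higher Med26 signal; with their kept shares weighted to the signal deciles of the regions away from Pol II, a step chosen after seeing the data, 2.74% were kept against the 1.13%. The share was higher at Pol II in all 10 deciles, of which the highest held only 14 regions away from Pol II. Of the highest decile of control Med26 regions by signal, 38.2% were kept, and of the lowest decile 0.167%. In the 953 windows listed in both libraries the median log2 difference, Cbx3 siRNA minus control, was -0.64 (interval -0.68 to -0.60), and 91.1% of these windows were lower after the knockdown. A window enters that median only if it lies above the minimum in both libraries. With equal numbers of regions, 22.9% of the 1745 highest control regions were kept.

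Cdk8 did not lose listed length: it covered 498 kb under control siRNA and 548 kb under Cbx3 siRNA. Its control regions were nonetheless mostly different from those after the knockdown, with 633 of 5574 kept (11.4%, interval 10.5 to 12.2%). The highest decile by signal was kept in 81.7% of cases, while each of the lowest 7 deciles was kept in 2.15% or fewer. On chromosome 8 from 112089351 to 112090000 Cdk8 went from 650 to 100 bp, and on chromosome 7 from 51629201 to 51629800 from 450 bp to none. It went from 100 to 600 bp on chromosome 17 from 56904001 to 56904600, and from none to 500 bp on chromosome 8 from 72566451 to 72566950. In the 2461 windows of both libraries the median log2 difference was 0.10 (interval 0.08 to 0.12). Single windows made up 63.4% of the control regions, so much of the Cdk8 list rests on few reads.

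Pol II was listed over 5800 kb under control siRNA and 5055 kb under Cbx3 siRNA, and 10915 of 16073 control regions were kept (67.9%, interval 67.2 to 68.6%). Every one of the 3 highest deciles was kept in over 99% of cases. The largest losses were on chromosome 3 from 96361501 to 96367000 (5200 to 3450 bp), chromosome 2 from 35316651 to 35318600 (1800 to 400 bp) and chromosome 3 from 121129001 to 121130800 (1800 to 650 bp). All 10 regions with the largest losses held Cbx3 of set 1, and 2 held Cbx3 of both sets; ranking by listed length picks long regions. Over all Pol II regions with windows in both libraries, those with Cbx3 of set 1 had a mean log2 difference of -0.28, against -0.27 in lists matched on signal (percentile 32.5). The largest gains were on chromosome 2 from 24124501 to 24125550 (none to 1050 bp), chromosome 5 from 77694051 to 77695850 (650 to 1650 bp) and chromosome 2 from 24006151 to 24007300 (none to 950 bp). In 74288 windows of both libraries the median log2 difference was -0.29.

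**Figure D2:**
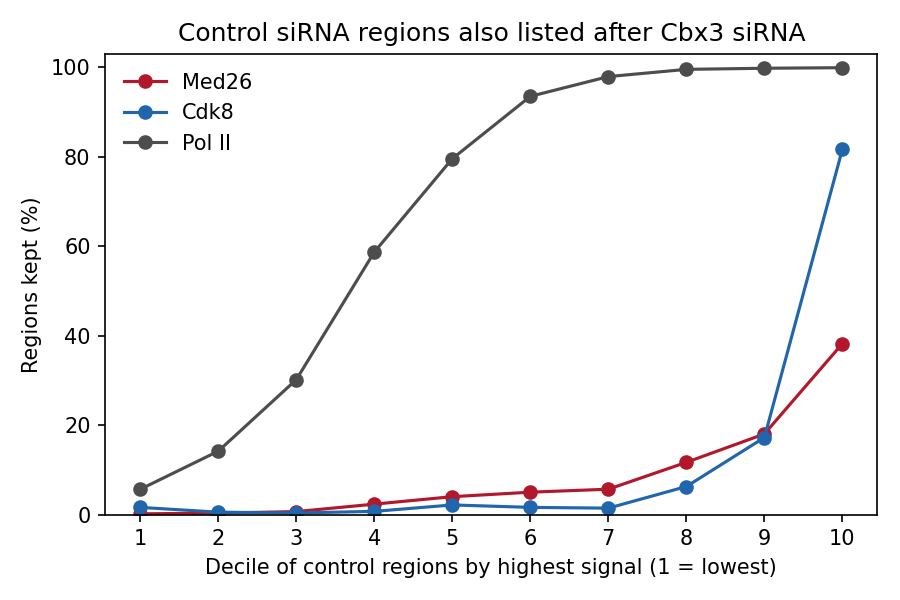
Control siRNA regions were split into deciles by their highest signal (horizontal axis), and points give the percent also listed after Cbx3 siRNA (vertical axis) for Med26, Cdk8 and Pol II. In the highest decile 38.2% of Med26, 81.7% of Cdk8 and 99.9% of Pol II regions were kept.

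Untreated and control siRNA cells gave the only comparison of Pol II libraries without a knockdown. Of the untreated regions, 94.9% (interval 94.4 to 95.3%) were listed under control siRNA and 91.5% under Cbx3 siRNA. With the 8183 highest regions of each library, untreated and control shared 86.3%, untreated and Cbx3 siRNA 81.1%, and control and Cbx3 siRNA 85.0%. Control and Cbx3 siRNA thus shared about as many top regions as the pair without a knockdown. That pair is no replicate pair, since the untreated cells had no siRNA. The 8183 regions are also the whole untreated list, whose lowest signal was 9.02 against 6.01 in the control list. The likeness of the shares therefore does not show that the knockdown left Pol II sites unchanged. In 32821 windows of both libraries the median log2 difference, control siRNA minus untreated, was 0.60, larger in size than the -0.29 seen between the siRNA arms; the step of the values differs between untreated and control.

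The last comparison asked whether the differences went with Cbx3 occupancy. Med26 was kept at 40 of the 266 control regions with Cbx3 of both sets (15.04%, interval 11.2 to 19.8%), and lists matched on control Med26 signal kept 11.7% (95% of lists from 8.27 to 15.4%). Cdk8 was kept at 23.7% of its Cbx3 regions and at 26.1% in matched lists. Pol II was kept at 83.5% of its Cbx3 regions, above the 80.5% of matched lists (95% of lists from 78.7 to 82.2%). Among 10554 Pol II regions with windows in both libraries, the mean log2 difference was -0.26 at those with Cbx3 of both sets and -0.27 in matched lists. It was -0.30 at Pol II regions where Med26 was lost and -0.32 where Med26 was kept, with -0.29 and -0.30 in matched lists. These gaps were small: the value where Med26 was lost lay at percentile 0.36 of its matched lists, and that where Med26 was kept at percentile 5.77. The percentiles rest on 3611 lost and 499 kept regions, and the gap itself was not larger where Med26 was lost. All Pol II regions with control Med26 together lay at percentile 0.05. The lower percentile where Med26 was lost thus does not tie the Pol II difference to Med26 loss. In these libraries Med26 was not kept less often at Cbx3 regions than at others of like signal. The lists were not matched on region width, however. Med26 control regions of 2 or more windows were kept in 12.6% of cases and single windows in 1.46%. Wider regions may also overlap Cbx3 more often, so a loss of Med26 at Cbx3 regions is not excluded.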

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

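All tests in this part but 1 were chosen after the result was seen; the exception is the distance between the Cbx3 sets.

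Med26 and Cdk8, both parts of Mediator, changed with opposite signs under the same contrast, Cdk8 only slightly. Listed windows changed by -82.5% for Med26 and by 9.99% for Cdk8, and the median log2 difference in windows of both libraries was -0.64 and 0.10. The difference between the factors was not tested, with 1 library per arm. The labels give the Med26 arms inputs of their own, apart from the other siRNA inputs. A difference between preparations can therefore not be told apart from one between the factors.

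For the fall of Med26, a different value per read is argued against, since the step was 0.0192 in both libraries; a difference in depth stays open. A single uniform loss was simulated by thinning all control windows to 26.3% of their reads. The factor was set so that as many windows stayed as both libraries listed. Listed counts were taken as true means, so windows not listed again through noise enter the factor. Cdk8 listed only 24.7% of its control windows again, with a median log2 difference of 0.10. The 26.3% is thus no measure of Med26 loss. The largest gap to the kept share per decile was 20.8 points with windows drawn independently. It was 7.61 points with 1 draw per region, a version added because neighbouring windows share reads. The observed 38.2% in the highest decile lies between the 59.1% and 32.9% of these draws, but of the 10 deciles 4 lie above both draws and 3 below both, 1 of these 7 by more than its counting interval, so a uniform loss is neither excluded nor shown. The draws do not cover the 1229 of 1745 regions listed after the knockdown alone, which thinning of listed control windows cannot give, and a weaker pulldown and an effect of the knockdown cannot be told apart without a replicate. Loss where Cbx3 is bound predicts a low kept share there. The share lay at percentile 96.5 of lists matched by quintiles of signal and 89.6 with 20 bins. Neither version matched region width, so such a loss is not excluded. Loss at listed Cbx3 regions alone predicts few lost regions without Cbx3. Of the 5474 lost regions, 73.4% (interval 72.2 to 74.6%) held neither Cbx3 set, but so did 4307 of all 5990 control regions. Cdk8, whose listed length did not fall, kept only 11.4% of its control regions, so a region not listed again need not have lost signal. The 73.4% therefore does not decide where Med26 was lost, and Cbx3 below the minimum of the lists stays open.

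The 2 Cbx3 sets listed mostly different regions. The overlap was 8.59 times as high in the highest as in the lowest decile of set 2, so windows of few reads near its minimum may contribute. In reverse, 3.29% of the 419145 set 1 regions overlapped the smaller set 2, from 0.721% in the lowest to 13.7% in the highest decile. Set 1 regions of decile 9 had signals of 42.7 to 47.8, against a minimum of 6.05, and only 4.60% overlapped. These regions lie well above the lowest listed signal of set 1. The threshold behind that list is unknown, though, and set 2 lists fewer windows. Weak signal is therefore not excluded as a source of the low share. Of set 2 regions outside set 1, 41.1% had a set 1 region within 1 kb against 25.9% after shifting, 1.59 times as many, so broad domains sampled at different places may also contribute. The design gives no biological difference between the sets, so none was tested.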

How the results depend on the processing

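Alternatives fixed before the data were examined cover overlap, threshold, equal numbers, merging and single Cbx3 sets; the others named here were chosen after seeing the data. Only the ratio of strong Pol II regions changed its direction, and the cause of the changes was not tested. A share or median is printed where it left the counting interval of the reported one, which is narrow here. With at least 50% of the shorter region, the kept share of Pol II was 66.7%, the Cbx3 set overlap 10.5%, and Cbx3 covered 4.88% of untreated, 5.15% of control and 4.63% of Cbx3 siRNA Pol II regions. With the control and the Cbx3 siRNA regions both cut at the median control signal, the kept shares were 7.65% for Med26, 21.2% for Cdk8 and 75.1% for Pol II. With each Cbx3 set cut at its own median signal, the sets overlapped by 14.4%. With equal numbers of regions, 22.9% of the 1745 highest Med26 control regions were kept, and 86.3% of untreated Pol II regions were listed under control siRNA. Without merging, Pol II kept 66.0% and the Cbx3 sets overlapped by 10.8%. With either Cbx3 set alone, Cbx3 covered 8.91 to 36.9% of untreated Pol II, 11.8 to 39.7% of control Pol II, 10.4 to 35.2% of Cbx3 siRNA Pol II, 5.84 to 25.2% and 3.78 to 15.5% of control and Cbx3 siRNA Med26, and 5.97 to 13.9% and 6.02 to 15.01% of control and Cbx3 siRNA Cdk8 regions. Of the added alternatives, counting windows above the control median left Med26 at 7.77%, Cdk8 at 111% and Pol II at 70.8% of control, against 17.5%, 110% and 87.1% for all windows. In shared windows above their median mean signal the median log2 differences were -0.87, 0.18 and -0.34 for Med26, Cdk8 and Pol II. The ratio of strong Pol II regions found after Cbx3 siRNA alone to those in control alone was 3.24 at a signal of 20, 1.02 at 6, 0.933 at 10, 1.27 at 15 and 9.67 at 30. For Med26 at Cbx3 regions, the excess over matched lists of 3.36 points stayed positive, from 2.21 to 4.46 points, under all 5 alternatives. None of these matched region width. The promoter windows, start sites and gene lists were not run. No paired analysis was possible because each siRNA arm had 1 library per antibody. Few reads per window limit Cbx3, Cdk8 and the Med26 Cbx3 siRNA library, in which 64.4% of regions are single windows.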

Other observations

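The tests in this part were all chosen after the result was seen, and the signal limit of 20 was picked after several had been looked at.

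Cdk8 windows were more concentrated than those of the other factors. The 6 stretches of 1 Mb with the most control Cdk8 windows held 7.48% of the control windows, 7.26% of the Cbx3 siRNA windows and 25.9% of the windows listed in both. The 6 fullest stretches of each other library held from 1.21 to 3.33% of its windows. Leaving out the stretch on chromosome 17 from 39 to 40 Mb, which holds a locus listed in all 9 libraries, the share for control Cdk8 was 6.96%. On chromosome 13, the stretch from 23 to 24 Mb held 184 Cdk8 windows under control and 213 under Cbx3 siRNA, and also 351 of the untreated Pol II windows, while control Med26 had 20 there. The stretch from 21 to 22 Mb held 175 and 177 Cdk8 windows. The Med26 and Cdk8 lists shared few regions: 155 of the 5990 control Med26 regions (2.59%) held Cdk8, against 0.0492% after shifting. Only 8.61% of control Med26 and 11.4% of control Cdk8 regions were listed again in the same factor's Cbx3 siRNA library. The low share therefore does not show that the 2 factors lie at different sites. Of the control regions, 74.9% of Med26 but 20.8% of Cdk8 lay at Pol II. That share was 35.4% in the lowest and 97.7% in the highest signal decile for Med26, and 13.1% and 40.4% for Cdk8. In all 9 libraries 10 stretches were listed, among them chromosome 9 from 44688451 to 44690450 and chromosome 17 from 39979851 to 39985900.

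At a signal of 20 or more, 243 Pol II regions were listed in the Cbx3 siRNA library and not in the control, and 75 the other way (a ratio of 3.24), although strong regions in total were fewer after the knockdown (5689 against 7201). The strongest 2 of the 243 were single windows on chromosome 17 at 39982701 and 39983151, inside the stretch listed in all 9 libraries; without such stretches the ratio was 3.26. Untreated Pol II covered 2.88% of the 243, 41.3% of the 75 and 88.8% of the strong regions in both. This contrast was largely fixed by the selection. The 243 lack a control region by definition, while 94.9% of all untreated regions overlapped one. The Cbx3 siRNA share of strong regions found in 1 library was 76.4% (interval 71.5 to 80.7%), but this restates the counts at a limit picked after several, so a chance difference between the 2 libraries stays open; the ratio was 1.02 at a signal of 6, 0.933 at 10, 1.27 at 15 and 9.67 at 30 (58 against 6). Cbx3 set 1 covered 2.88% of the 243 (interval 1.40 to 5.83%) against 6.33% after shifting, and set 2 covered 2.47% (1.14 to 5.28%) against 1.93%. Either set covered 3.29%, which argues against gain at listed Cbx3 regions as the cause. Med26 or Cdk8 of the same knockdown lay at 2.06% of the 243. Of the strong Pol II regions in both libraries only 11.6% held that Med26 and 15.1% that Cdk8. Such sparse lists cannot test for DNA shared with those libraries, which stays open. DNA from elsewhere or Pol II gained at sites with no listed Cbx3 may also account for the 243, and neither was tested.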
